A study of Arabidopsis thaliana with 12 samples.

How the data were processed

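Total RNA from shoots of 14-day-old Arabidopsis thaliana seedlings was labelled with biotin and hybridized to Affymetrix ATH1 arrays, 12 in all. The labels place the arrays in 4 groups of 3 biological replicates, which combine the genotype (Col-0 or the avp1 mutant lcs7) with the calcium of the agar medium (2 or 0.3 mM). Groups were taken from the labels alone.

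The deposited values are probe set intensities on a linear scale, 22746 per array, with 1 decimal and a floor of 0.1. The mean deposited intensity of an array over its probe sets, without the highest and lowest 2%, was nearly equal in all, from 495.4 to 496.0. Per the labels, the authors used RMA, with no version given, and oligo 1.32.0. The deposited values are neither log2 values nor on shared quantiles, as RMA output would be, so the summarisation method behind them is not known. Arrays give no read depth, and the 3 arrays per group set the precision. Between 17.1 and 19.3% of the probe sets of an array had a signal under 20, where values near the floor give wide errors on the log2 scale.

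Signals were taken to log2 with no offset. Of the 22746 probe sets, the annotation used here names a gene for 14016, of which 13513 name 1 gene and 503 name several. Probe sets of several genes or of no named gene were left out of the tests, since a change in them cannot be given to 1 gene. Of several probe sets of 1 gene, the one with the highest mean over all arrays was kept, which left 13356 genes. A symbol was given for 1557 of these and only a locus identifier for the other 11799. The probe set of AVP1 is not among the named ones and is not analysed here.

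Differences were tested with limma 3.58.1 in R 4.3.3: 1 mean per group over all 12 arrays, empirical Bayes moderation, 2-sided tests and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at an adjusted p under 0.05 with no fold limit. The 4 simple comparisons were lcs7 against Col-0 at each calcium level and 0.3 against 2 mM calcium in each genotype, and the interaction was the difference between the genotype effects at the 2 calcium levels. Similarity between comparisons was described across genes with Pearson's r and Spearman's rho. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

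The comparisons, the tests, the alternatives, 45 gene lists and the rule for named genes were fixed before the data were examined. Another 23 lists were written once the annotation had shown which genes carry symbols, before any value of a list was computed. Because few genes carry symbols or could be matched by locus, 11 of the 45 lists fixed first had no measured member and 24 had from 1 to 4. Lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The named genes were AVP1 and, per simple comparison, the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups and whose probe set is not marked as shared between genes, 5 in each direction for the interaction, and up to 4 called members of each list, or 2 members with the smallest p where none was called.

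The alternatives were an intensity trend or robust moderation, array weights, quantile normalization, median centring, leaving out the 40% dimmest genes, the mean over the probe sets of a gene, all probe sets, a fold of at least 2, only the compared groups in the fit, the replicate number as a term of the model, and each array left out in turn. Alternatives chosen after the data were seen were an offset of 50, a mean signal of at least 100 in some group, and leaving out Col-0 replicates 2 and 3 at 0.3 mM calcium. The tests were run on simulated data with known changes in 200 of 13356 genes. They recovered from 14 to 22% of the genes changed 1.5-fold in the simple comparisons and 0% for the interaction. For genes changed 2-fold the share was from 30 to 52%, and for those changed 8-fold from 68 to 74%. There were 5 to 10 false calls per comparison and none in the wrong direction. The simulated noise was independent between genes, and few genes were changed, so these shares may not hold for comparisons with many calls.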

Results

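Gene expression was measured in shoots of 14-day-old seedlings of the wild type Col-0 and of lcs7, a mutant of AVP1, the gene of the vacuolar proton-pumping pyrophosphatase. Both lines grew on agar with 2 mM or 0.3 mM calcium, with 3 arrays in each of the 4 groups. The median signal of an array lay between 161.3 and 187.6, with lower quartiles from 30.7 to 37.3 and upper quartiles from 547.4 to 591.9. AVP1 itself was not analysed here, because no probe set carries its name, so its transcript level in lcs7 is open. Values below are log2 differences of group means with their SE (n = 3 arrays per group) and limma adjusted p, and signals are geometric means of the group. Gene lists with a count adjusted over the list alone were fixed before the data were examined, and the other lists were chosen after the annotation was seen. Where the lower of the signals was under 20, near background, the size of a difference and its place among the others are not well measured, and a lower bound with signals under 20 raised to 20 is given for the genes named first.

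The arrays of lcs7 at 0.3 mM calcium stood apart from all others along the first principal component, which held 55.3% of the variance. Their positions lay between 41.8 and 43.99, while the other 9 arrays lay between -29.91 and 1.34. The second component held 11.9% of the variance, and the lcs7 arrays at 2 mM calcium lay lowest on it, from -21.42 to -17.46.

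**Figure D1:**
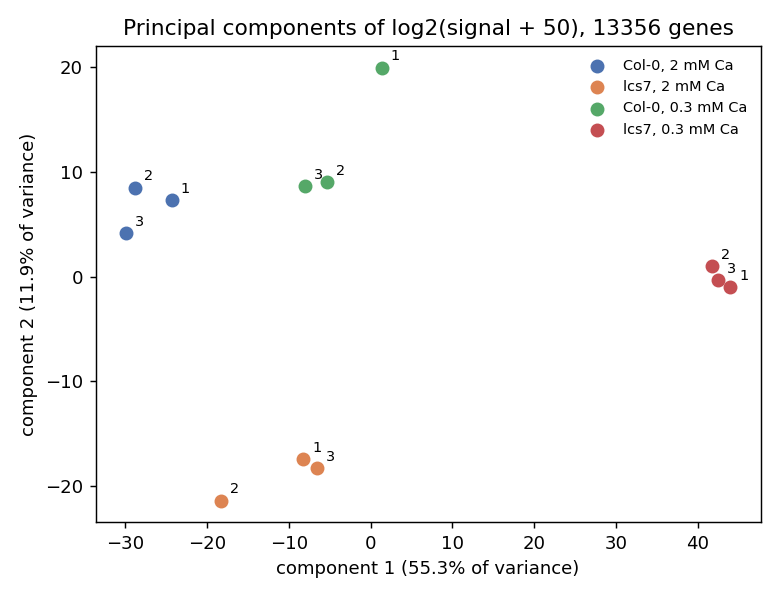
Each point is an array (n = 3 per group, numbered by replicate), placed by its first and second principal components of log2(signal + 50). The 3 arrays of lcs7 at 0.3 mM Ca sit near 42 on component 1, away from the other 9.

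Col-0 replicates 2 and 3 at 0.3 mM calcium carried part of the lcs7 signal at genes far below it in Col-0 at 2 mM calcium. These genes were chosen after the data were seen, as the 11 whose lowest lcs7 array was at least 8-fold above the highest Col-0 array at 2 mM calcium, at both calcium levels, with a signal of at least 300. On a scale from the Col-0 level at 2 mM (0%) to the lcs7 level at 0.3 mM (100%), the median over these genes was -0.1% in replicate 1, 25.5% in replicate 2 and 37.2% in replicate 3. The Col-0 arrays at 2 mM calcium had medians of 0, -0.3 and 0%. AT3G47250 had a signal of 23.4 in replicate 1, 581.1 in replicate 2 and 841.5 in replicate 3, against 2242 in lcs7 at 0.3 mM calcium. The histone gene HTB11 stood at 65.2 and 67.8% in replicates 2 and 3, whereas AT5G24240 stood at 1.3 and 1.5%. Every comparison that uses Col-0 at 0.3 mM calcium includes these arrays, and the counts without them are given with each. By other measures replicate 1 stood apart from replicates 2 and 3. Its array weight was the lowest of all arrays, 0.579, against 0.934 in replicate 2 and 0.893 in replicate 3. On the second principal component it lay at 19.99, against 9.04 and 8.67. Which of these Col-0 arrays are atypical was thus not settled.

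**Figure D2:**
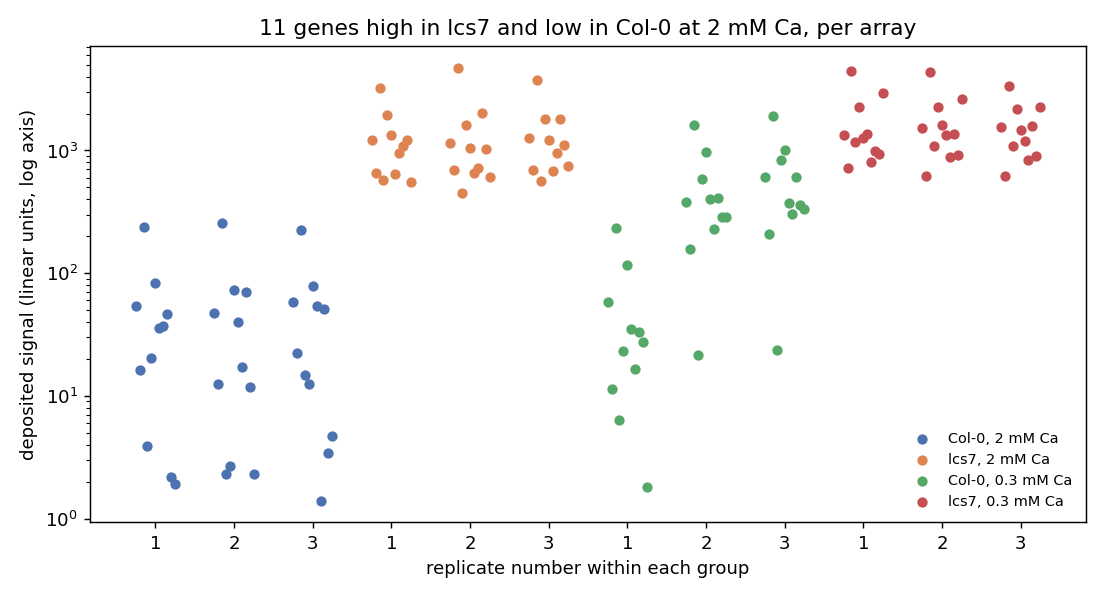
Deposited signal (log axis) of the 11 genes in each array, by group and replicate number. In Col-0 at 0.3 mM Ca, replicate 1 lies with Col-0 at 2 mM Ca, and replicates 2 and 3 lie between Col-0 and lcs7.

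The comparison of lcs7 with Col-0 at 2 mM calcium asks how the mutant line differs at the higher calcium supply. Of the 10 largest rises 9 were at genes with a signal under 20 in Col-0. AT1G23960 was higher by 7.97 ± 0.91 (at least 5.81; adjusted p = 0.00476; signal 4.46 in Col-0 and 1121 in lcs7), AT5G24240 by 6.70 ± 0.67 (at least 4.72; adjusted p = 0.00225) and QQS, an orphan gene linked to leaf starch content, by 5.62 ± 0.54 (at least 4.67; adjusted p = 0.002; signal 10.3 and 508). Of the 10 largest falls 9 were at genes with a signal under 20 in lcs7. AT3G28320 fell by 4.91 on the log2 scale (SE 0.72, adjusted p = 0.0104; signal 699 in Col-0 and 23.3 in lcs7). BHLH101, a transcription factor of the iron deficiency response, was lower at -3.31 ± 0.45 (or -0.97 with the lower signal at 20; adjusted p = 0.00815), with signals of 39.1 and 3.95. The other large rises were AT1G76960, AT3G47250, AT3G43740, AT3G44400, AT1G80960, AT5G51620 and AT4G02540, from 4.85 to 7.85, and the other large falls ranged from -4.03 to -2.44, at genes with a signal under 100 in Col-0.

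Among the groups, PYK10, a beta-glucosidase abundant in roots, rose by 1.44 ± 0.17 (adjusted p = 0.00491), the only one of the 3 measured root markers that passed (1 when adjusted over the list alone). Of the 4 jacalin lectins, JAL33 (1.60 ± 0.22) and JAL22 (1.36 ± 0.21) rose, and JAL34 (0.96 ± 0.23, adjusted p = 0.0659) and JAL23 (0.10 ± 0.30) did not pass. Of the 4 measured genes of the list for abscisic acid, drought and cold, COR15A, a chloroplast protein of cold acclimation, rose by 2.44 ± 0.35 (adjusted p = 0.00951) and the dehydrin LTI30 by 1.18 ± 0.24, and 3 rose when adjusted over the list alone. The light-harvesting gene LHCB4.2 (0.99 ± 0.21) was the 1 of 11 photosynthesis genes that rose (1 when adjusted over the list alone), CHLI2 of magnesium chelatase (0.71 ± 0.11) was the 1 of 11 chlorophyll synthesis genes, and 1 of 7 tubulins, TUB1, fell (-0.90 ± 0.17). GSTU26 was the 1 of 14 glutathione transferases that rose (1.47 ± 0.18, and 1 when adjusted over the list alone). The 18 defence and immunity markers shifted upward as a set (camera adjusted p = 0.0186), with 1 called member, PDF1.4 (1.16 ± 0.21). With an estimated correlation that set had an adjusted p = 0.622, and its adjusted p under the other alternatives ran from 0.00321 to 0.229, over 0.05 with fry and without Col-0 replicate 3 or lcs7 replicate 3 at 2 mM calcium. The 2 measured subunits of the vacuolar proton ATPase, VHA-A3 (-0.09 ± 0.11) and VHA-A2 (0.03 ± 0.11), had differences within 1 SE of 0 (adjusted p = 0.774 and 0.944; limma called 0 of 2, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05).

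At 2 mM calcium, 367 of 13356 genes were called, 219 higher and 148 lower in lcs7, and 189 of them differed at least 2-fold. The arrays of the groups did not overlap in any of the 367, and in 21.4% of all genes, where chance gives 10%. Of 35 calls at the named genes 13 passed in each of the 12 fits without 1 array, among them AT1G23960, AT3G28320, QQS, PYK10 and COR15A, while CHLI2 passed in 10, TUB1 in 8, PDF1.4 in 7, LTI30 in 3 and LHCB4.2 in 2. With only the compared groups in the fit the count was 83. It moved by over 1.5 times without Col-0 replicate 1, 2 or 3 at 2 mM calcium (173, 151 and 156), lcs7 replicate 1 or 3 at 2 mM (164 and 138) or lcs7 replicate 2 or 3 at 0.3 mM (231 and 240).

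**Figure D3:**
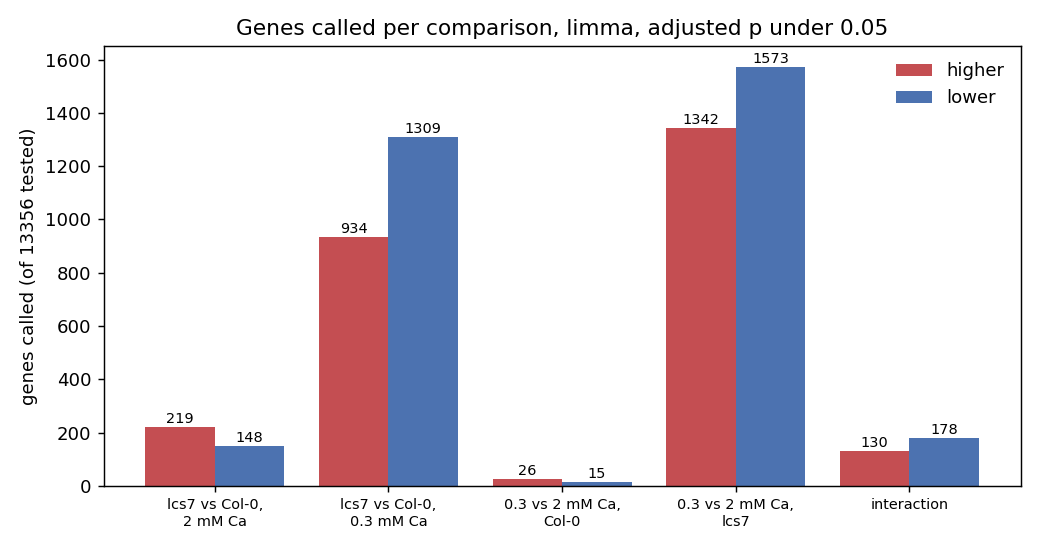
Bars give the number of genes called higher (red) and lower (blue) in each comparison (limma, adjusted p under 0.05, n = 3 arrays per group). The calls for low calcium numbered 1342 higher and 1573 lower in lcs7, and 26 higher and 15 lower in Col-0.

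The same comparison at 0.3 mM calcium asks how the line differs when calcium is low. Of the 10 largest rises 8 were at genes with a signal under 20 in Col-0 and 1 of these, AT5G24240, was also high in lcs7 at 2 mM calcium. AT2G44240 was higher by 7.80 ± 0.62 (at least 5.59; adjusted p = 0.000251; signal 4.35 in Col-0 and 966 in lcs7), AT1G76640, a calmodulin-like gene, by 6.96 ± 0.37 (at least 3.62; adjusted p = 4.18e-05), and LCR67, a defensin-like gene, by 6.54 ± 0.99 (at least 5.06; adjusted p = 0.00252). All 10 largest falls were at genes with a signal under 20 in lcs7. AT3G28320 was lower again, at -5.31 ± 0.72 (or -4.44 with the lower signal at 20; adjusted p = 0.00163). WSD1, a wax ester synthase, was lower (-1.64 with the lower signal at 20; adjusted p = 0.00409), with signals of 62.3 and 3.89. The other large falls ranged from -4.15 to -3.52 at genes with a signal under 25 in both lines.

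Many defence genes were higher in lcs7. Of the 18 defence and immunity markers 9 rose (camera adjusted p = 1.28e-06), including OSM34 (4.67 ± 0.37), THI2.1 (4.06 ± 0.37) and UGT76B1 (3.69 ± 0.77). Both measured salicylic acid response genes rose, GRX480 by 2.73 ± 0.41 and SAG101 by 1.35 ± 0.12 (also 2 when adjusted over the list alone). Of 47 UDP-glycosyltransferases 10 rose and 1 fell (camera adjusted p = 0.000228), such as UGT73B4 (4.61 ± 0.46, or 3.17 with the lower signal at 20). Of 19 CYP71B cytochromes P450 6 rose, such as CYP71B36 (1.74 ± 0.23) and CYP71B6 (1.42 ± 0.14) (camera adjusted p = 0.00271). All 3 measured anthocyanin genes rose (3 when adjusted over the list alone): DFR by 1.89 ± 0.21, UF3GT by 1.68 ± 0.31 and AT5MAT by 1.31 ± 0.14. All 4 jacalin lectins rose, JAL23 most (3.37 ± 0.30), and PYK10 rose by 1.92 ± 0.17. At an estimated correlation the adjusted p was 0.138 for the defence markers, 0.0816 for the glycosyltransferases and 0.221 for CYP71B.

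Several calcium sensors were higher and many chloroplast genes lower. Of 8 calcium sensors 3 rose, AT1G76640, CML41 (1.93 ± 0.24) and CML43 (1.91 ± 0.23), and CML30 fell (-0.98 ± 0.14), while 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00128). CaS, a thylakoid calcium-sensing protein and the 1 measured gene of the list of calcium transporters and channels, fell by 0.93 on the log2 scale (SE 0.13, adjusted p = 0.00171; 1 when adjusted over the list alone). Of 25 nuclear genes for plastid assembly and RNA editing 14 fell (camera adjusted p = 1.39e-05), including NdhL (-1.17 ± 0.13) and LPA2 (-1.04 ± 0.11). Of 11 photosynthesis genes 6 fell, such as PSBY (-0.70 ± 0.09) and PSAN (-0.69 ± 0.13), and LHCB4.3 rose (0.79 ± 0.20), with the same counts when adjusted over the list alone (camera adjusted p = 0.0113). Of 11 chlorophyll synthesis genes 5 fell, CHLM most (-0.94 ± 0.09; camera adjusted p = 0.00392), and 5 of 7 tubulins fell, such as TUB5 (-0.90 ± 0.13; camera adjusted p = 0.00128). With an estimated correlation the adjusted p was 0.138 for the calcium sensors, plastid assembly and chlorophyll synthesis, 0.313 for photosynthesis and 0.232 for the tubulins. Under the alternatives the photosynthesis set ran from 0.00236 to 0.138, its highest with quantile normalization. Camera also passed endoplasmic reticulum stress (adjusted p = 0.00289), the plastid-encoded photosynthesis genes (0.00289), the glutamate receptor-like and cyclic nucleotide-gated channels (0.0175), GH9 endoglucanases (0.0297) and the early elicitor genes (0.0322), with adjusted p of 0.15, 0.53, 0.309, 0.313 and 0.313 at an estimated correlation. Of 8 channels 2 rose and 1 fell, or 5 and 1 when adjusted over the list alone, and of 5 early elicitor genes limma called 0 over all genes, with 4 higher at an unadjusted p under 0.05 and 4 when adjusted over the list alone. Under the other alternatives the highest adjusted p of these 5 sets with camera was 0.0117, 0.0969, 0.168, 0.402 and 0.107, and the lowest 0.00121, 1.88e-07, 0.00801, 0.0115 and 0.00259. Fry, which does not compare a set with other genes, gave 0.105 for the plastid-encoded genes and under 0.05 for the other 4. Without Col-0 replicates 2 and 3 at 0.3 mM calcium the GH9 endoglucanases (0.402) and the channels (0.125) did not pass.

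Of the 13356 genes 2243 were called at 0.3 mM calcium, 934 higher and 1309 lower in lcs7, and of the 806 that differed at least 2-fold 481 were higher and 325 lower. Median centring gave 790 higher and 1659 lower. The arrays did not overlap in 35.7% of all genes, where chance gives 10%. Without Col-0 replicates 2 and 3, with the lone Col-0 array assumed to vary like the other groups, 747 genes were called (416 higher and 331 lower), of which 595 were among the 2243, and 59 of the 120 calls at the named genes passed, while 90 of the 120 passed in each of the 12 fits without 1 array. Keeping only replicate 3 or only replicate 2 of Col-0 also lowered the count, to 1121 and 986, so part of the fall comes with the loss of arrays. Without lcs7 replicate 3 at 0.3 mM calcium the count was 1493.

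Low against high calcium in Col-0 asks how the wild type responds to the lower supply. The lower signal was under 20 at 6 of the 10 largest rises and 3 of the 10 largest falls. AT3G28220, a gene of the TRAF-like family, rose by 5.04 ± 0.36 (adjusted p = 0.00175), from a signal of 26.9 to 884. AT5G55420 rose by 3.88 ± 0.51 (at least 1.74; adjusted p = 0.0307), and the neighbours AT5G52760 and AT5G52750, with heavy-metal-associated domains, rose by 2.49 ± 0.22 (adjusted p = 0.00697) and 2.22 ± 0.27 (adjusted p = 0.0261). AT1G67000, a receptor-like kinase gene, rose by 2.56 ± 0.27 (at least 0.13; adjusted p = 0.014; signal 3.71 to 21.9), and AT1G06000, a flavonol glycosyltransferase gene, by 2.15 ± 0.33 (adjusted p = 0.0424). At 2 mM calcium AT3G28220, AT5G52760 and AT5G52750 were also higher in lcs7 than in Col-0, by 7.72-, 3.67- and 3.58-fold. So were AT1G23140 and AT1G10160, other large rises here, by 12.7- and 9.66-fold. AT1G67000 (1.26-fold) and AT1G06000 (1.65-fold) differed less. Both comparisons use the same Col-0 arrays at 2 mM calcium, and whether these rises are line differences was not tested. Among the falls, AT3G05900 was lower at -1.60 ± 0.23 (adjusted p = 0.037) and the remorin gene AT3G61260 at -0.84 ± 0.11 (adjusted p = 0.0301; signal 5736 and 3205).

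In the gene lists few members were called singly. The defence and immunity markers shifted upward (camera adjusted p = 3.56e-06) with 0 of 18 called by limma over all genes and 9 higher at an unadjusted p under 0.05. WRKY53 (2.22 ± 0.39) and PDF1.4 (1.18 ± 0.21) each had an adjusted p = 0.0503. The 5 early elicitor and wound response genes also shifted upward (camera adjusted p = 0.0122), with 0 called by limma over all genes, 3 higher at an unadjusted p under 0.05 and 3 rising when adjusted over the list alone. The 47 plastid-encoded photosynthesis genes shifted downward (camera adjusted p = 3.06e-12; median -0.63) with 0 called by limma and 23 lower at an unadjusted p under 0.05, for example psbA (-0.72 ± 0.12, adjusted p = 0.0503), as did the 22 genes of the plastid gene expression machinery (camera adjusted p = 0.00356) and the 7 tubulins (camera adjusted p = 0.0176), each with 0 called by limma and with 2 and 3 lower at an unadjusted p under 0.05. JAL23 rose by 1.96 ± 0.30 (adjusted p = 0.0435), the 1 of 4 jacalin lectins that passed. An estimated correlation gave an adjusted p of 0.489 for the defence markers, 0.516 for the early elicitor genes, the plastid-encoded photosynthesis genes and the tubulins, and 0.584 for the expression machinery. Without Col-0 replicates 2 and 3 at 0.3 mM calcium the camera adjusted p was 0.18 for the early elicitor genes (range of camera over the alternatives 0.00352 to 0.18), 0.247 for the expression machinery (7.92e-05 to 0.247) and 0.0532 for the tubulins (0.0063 to 0.108). Fry, which does not compare a set with other genes, gave an adjusted p of 0.272 for the expression machinery and 0.0707 for the early elicitor genes, the plastid-encoded photosynthesis genes and the tubulins.

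In Col-0, 41 of 13356 genes were called, 26 higher and 15 lower at 0.3 mM calcium, 31 of them at least 2-fold, and 2337 genes had an unadjusted p under 0.05. The arrays did not overlap in any of the 41, and in 22.3% of all genes, where chance gives 10%. Without replicates 2 and 3 at 0.3 mM calcium 75 genes were called, 10 of them among the 41, and with only the compared groups in the fit limma called 0, with 1716 at an unadjusted p under 0.05. Leaving out 1 array gave 17, 14 and 9 for Col-0 replicates 1, 2 and 3 at 2 mM, 79 and 22 for lcs7 replicates 1 and 3 at 2 mM, 9 and 12 for Col-0 replicates 2 and 3 at 0.3 mM, and 10, 6 and 11 for lcs7 replicates 1, 2 and 3 at 0.3 mM, while the calls of AT3G28220, AT1G67000 and AT5G52760 passed in each of the 12 fits without 1 array, 3 of 21 at the named genes. AT5G52750 passed in 7 of these fits, AT5G55420 in 6, AT3G61260 in 4, JAL23 in 3, and AT1G06000 and AT3G05900 in 2. Without Col-0 replicates 2 and 3 at 0.3 mM, 5 of the 21 passed, with AT3G28220 and AT5G52760 but without AT1G67000.

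Low against high calcium in lcs7 asks the same of the mutant. Of the 10 largest rises 8 started from a signal under 20. AT2G44240 rose by 8.06 ± 0.62 (at least 5.59; adjusted p = 0.000135; signal 3.61 to 966), the jasmonate-regulated gene JRG21 by 7.15 ± 0.91 (at least 5.81; adjusted p = 0.000813) and AT1G76640 by 7.03 ± 0.37 (at least 3.62; adjusted p = 5.68e-05). Also among the 10 were LCR67 (6.33 ± 0.99, at least 5.06), CHI (6.31 ± 1.04; signal 39.9 to 3164), AT1G54020 (5.99 ± 0.51; signal 22.2 to 1419), CML37 (5.88 ± 0.93, at least 3.07) and the peroxidase gene PRX52 (5.77 ± 0.96, at least 4.24). All 10 largest falls ended at a signal under 20: AT3G46370 fell by 5.20 on the log2 scale (SE 0.86, or -2.14 with the lower signal at 20; adjusted p = 0.00268; signal 88 to 2.4) and AT5G62280 by 4.22 (SE 0.65, or -3.29; adjusted p = 0.00197; signal 195 to 10.5).

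Many stress and defence genes rose. Of the 18 defence and immunity markers 13 rose (camera adjusted p = 2.65e-08), including THI2.1 (5.59 ± 0.37; signal 37.4 to 1804), OSM34 (4.63 ± 0.37) and PDF1.2 (4.32 ± 0.94). Of the 5 early elicitor and wound response genes 4 rose, CML37, WRKY53 (3.02 ± 0.39), the zinc finger gene STZ (2.96 ± 0.57) and CML38 (2.26 ± 0.51), also 4 when adjusted over the list alone (camera adjusted p = 0.00462). Of 8 calcium sensors 5 rose and CML30 fell (-1.12 ± 0.14), or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.000484). CML37 and CML38 belong to both of these lists, so the lists are not independent. Of 8 glutamate receptor-like and cyclic nucleotide-gated channels 4 rose, GLR2.8 by 2.38 ± 0.22, and GLR3.6 fell (-0.77 ± 0.17), or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.005). Of 14 genes of endoplasmic reticulum stress and degradation 5 rose, among them ATERDJ3B (1.27 ± 0.11) and CRT1b (1.07 ± 0.12), and DER2.1 fell (-0.46 ± 0.12; camera adjusted p = 0.0032). Of 47 UDP-glycosyltransferases 14 rose and 1 fell (camera adjusted p = 0.000673), and of 19 CYP71B genes 7 rose (camera adjusted p = 0.000322). All 3 anthocyanin genes rose, DFR by 2.56 ± 0.21 (3 when adjusted over the list alone), and so did 3 of 4 jacalin lectins, JAL23 by 5.23 ± 0.30. Estimating the correlation gave an adjusted p of 0.11 for the defence markers, calcium sensors and glycosyltransferases, 0.197 for the early elicitor genes, 0.192 for the channels and 0.149 for endoplasmic reticulum stress and CYP71B. The channels, the calcium sensors and the glycosyltransferases had camera adjusted p of up to 0.0771, 0.053 and 0.1 when dim genes were left out, from lowest values of 0.00269, 4.48e-06 and 0.000175 over the alternatives with camera.

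Among the falls were many chloroplast genes and some cold response and tubulin genes. Of 47 plastid-encoded photosynthesis genes 22 fell (camera adjusted p = 2.93e-11), such as psbC (-1.34 ± 0.35) and psbB (-1.30 ± 0.28). Of 11 photosynthesis genes 7 fell, LHCB4.2 most (-1.77 ± 0.21), and LHCB4.3 rose (1.19 ± 0.20), or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.000165). Of 11 chlorophyll synthesis genes 7 fell, among them PORB (-1.15 ± 0.18) and CHLM (-0.96 ± 0.09), and HEMA3 rose (1.92 ± 0.45, at least 0.78) from a signal under 10 (camera adjusted p = 0.00246). Of 25 plastid assembly and editing genes 10 fell (camera adjusted p = 8.74e-05), PSB27 most of the named ones (-1.13 ± 0.13). The plastid gene expression machinery, which also shifted in Col-0, had 4 of 22 genes lower (camera adjusted p = 0.00698, from 1.36e-05 to 0.0675 over the alternatives; 0.522 at an estimated correlation and 0.091 with fry). Of 7 tubulins 5 fell, TUB5 by 1.45 on the log2 scale (SE 0.13; camera adjusted p = 0.000742). Of the 4 genes for abscisic acid, drought and cold 3 fell, COR47 (-2.21 ± 0.19), COR15A (-2.04 ± 0.35) and COR15B (-1.69 ± 0.23), also 3 when adjusted over the list alone, while the wider list of 14 cold and dehydration proteins did not pass camera (adjusted p = 0.0983, and 0.261 at an estimated correlation). CaS fell by 1.06 on the log2 scale (SE 0.13), and the guard cell gene FMA, 1 of 3 stomatal markers, fell by 0.75 (SE 0.20, adjusted p = 0.0248; 1 when adjusted over the list alone), while PYK10 rose by 1.11 ± 0.17. The reference gene PEX4 had -0.19 ± 0.10 (adjusted p = 0.216) and was not called, nor when adjusted over the list alone. With an estimated correlation the adjusted p was 0.209 for the plastid-encoded genes, 0.183 for photosynthesis, 0.11 for chlorophyll synthesis, 0.149 for plastid assembly and 0.192 for the tubulins.

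**Figure D4:**
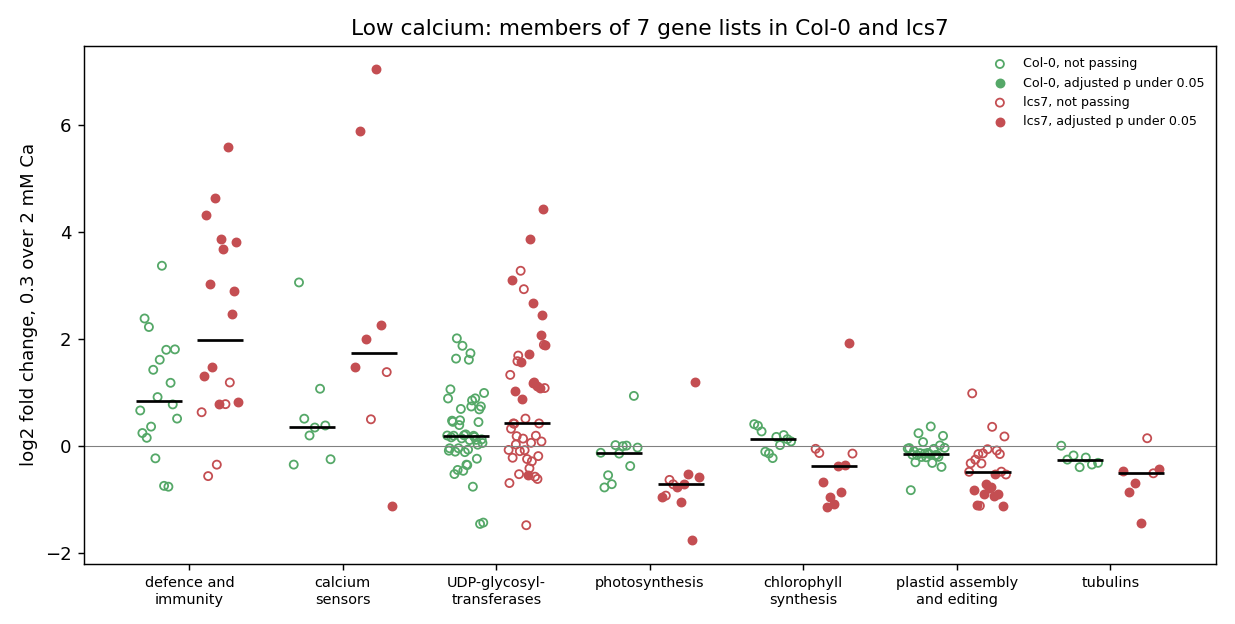
Each point is a gene of 1 of 7 lists, with its log2 fold change of 0.3 over 2 mM Ca in Col-0 (green) and lcs7 (red); filled points passed limma at an adjusted p under 0.05 and bars are medians. The median of the defence list was 0.84 in Col-0 and 1.97 in lcs7, and that of the photosynthesis list -0.13 and -0.72.

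In lcs7, 2915 of 13356 genes were called, 1342 higher and 1573 lower at 0.3 mM calcium, and of the 1072 that differed at least 2-fold 640 were higher and 432 lower. Of 140 calls at the named genes 105 passed in each of the 12 fits without 1 array. The arrays did not overlap in 41.7% of all genes, where chance gives 10%, and no alternative that kept the tested genes and set no fold limit moved the count by over 1.5 times. Median centring gave 1043 higher and 2196 lower and put the median of all genes at -0.169 here, and at -0.131 for lcs7 against Col-0 at 0.3 mM calcium, so the balance of rises and falls depends on the scaling and on the fold.

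The interaction asks whether the genotype difference changed with calcium. It was largest at AT2G44240 (7.83 ± 0.88, adjusted p = 0.0102) and AT1G76640 (6.69 ± 0.52, adjusted p = 0.00267), whose signals were under 5 in the other 3 groups. In the other direction AT3G43350 (-5.68 ± 0.91, adjusted p = 0.0197) and EC1.2 (-5.10 ± 0.95, adjusted p = 0.0317), known from egg cells, had signals under 25 in every group. BHLH101, low in lcs7 at 2 mM calcium, had a signal of 35.4 in lcs7 at 0.3 mM, and its interaction passed (adjusted p = 0.0447; 0.66 with signals under 20 raised to 20). QQS had an interaction of -3.99 ± 0.76 (adjusted p = 0.034), with a signal of 89.8 in Col-0 at 0.3 mM calcium.

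By group, the interaction was negative for chlorophyll synthesis (camera adjusted p = 5.88e-05), where CHLI2, CHLM and HEME1 were the called members of 11, for photosynthesis (camera adjusted p = 0.000116; 3 of 11 called, and 7 when adjusted over the list alone) and for plastid assembly (camera adjusted p = 0.000191; LPA2 called of 25). It was positive for the defence markers (camera adjusted p = 8.86e-05; 3 of 18 called, such as THI2.1 at 3.80 ± 0.52) and for the calcium sensors (camera adjusted p = 0.00141; 2 of 8 called, AT1G76640 and CML43, and 3 positive and 1 negative when adjusted over the list alone). When the correlation was estimated the adjusted p was 0.0603 for chlorophyll synthesis, 0.212 for photosynthesis, plastid assembly and the defence markers, and 0.193 for the calcium sensors.

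The interaction was called in 308 genes, 130 positive and 178 negative, with 187 at least 2-fold. Of the 10 calls named for the largest values 3 passed in each of the 12 fits without 1 array, among them AT2G44240 and AT1G76640, while AT3G43350 passed in 9 and EC1.2 in 3. Without Col-0 replicates 2 and 3 at 0.3 mM calcium limma called 0 genes, with 1869 at an unadjusted p under 0.05, against 136 and 89 when only replicate 3 or only replicate 2 was kept. The count moved by over 1.5 times without any 1 array except Col-0 replicate 1 at 0.3 mM calcium, to between 57 (without lcs7 replicate 3 at 0.3 mM) and 197 (without lcs7 replicate 3 at 2 mM).

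The genotype differences at the 2 calcium levels had r = 0.26 and rho = 0.248 across the 13356 genes, which are not independent replicates, and 60.6% of the genes had the same sign. Of 226 genes called at both levels, 123 were higher in lcs7 at both, among them PYK10, JAL33, AT5G24240 and AT5G52760, 97 were lower at both, such as AT3G28320 and TUB1, and 6 were opposite, such as AT5G15420. With signals under 20 raised to 20, AT5G15420 had -0.57 at 2 mM and 0 at 0.3 mM, so its reversal is not well measured. Independent calls would give 15.3 higher at both, 14.5 lower at both and 31.8 opposite. The comparisons share the variance estimate of each gene, so some overlap above such numbers can arise without shared effects, here and for the calcium responses. The calcium responses of Col-0 and lcs7 had r = 0.297 and rho = 0.33, with 65% of genes of the same sign. Of 31 genes called in both genotypes, 21 rose in both, such as AT3G28220, AT1G67000 and JAL23, 9 fell in both, such as the remorin gene AT3G61260, and 1 was opposite, against 2.6, 1.8 and 4.6 for independent calls. Among genes with a mean signal of at least 100 in some group, r was 0.56 for the genotype differences and 0.671 for the calcium responses.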

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

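The comparisons of counts at a signal of at least 100 and with an offset of 50, the fit without Col-0 replicates 2 and 3 at 0.3 mM calcium, the ratios with arrays of both genotypes left out and the ratios at an unadjusted p were tests chosen after the data were seen; the other tests of this part were chosen before.

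The effect of the genotype differed with calcium by the interaction test in 308 of 13356 genes. The largest values were positive at AT2G44240 (7.83), AT1G76640 (6.69), AT1G33760 (5.91), AT3G53600 (5.64) and AT5G15420 (5.10), and negative at AT3G43350 (-5.68), EC1.2 (-5.10), AT3G45940 (-4.97), AT3G43650 (-4.62) and AT3G46800 (-4.46). With group signals under 20 raised to 20, AT2G44240 (5.59), AT1G76640 (3.62) and AT1G33760 (3.26) kept values over 1, while the other 7 lay between -0.40 and 0.90, so the size of these 7 is not well measured. In the 12 fits without 1 array AT2G44240, AT1G76640 and AT5G15420 passed in each, AT3G43350 in 9, AT3G45940 and AT3G43650 in 8, AT3G53600 in 4, EC1.2 in 3, AT1G33760 in 2 and AT3G46800 in 1. Of 71 genes named for a large rise or fall, 16 also passed the interaction test. Without Col-0 replicates 2 and 3 at 0.3 mM calcium limma called 0 genes for the interaction (1869 at an unadjusted p under 0.05).

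Sets of genes also differed by the interaction, with camera at the preset correlation: chlorophyll synthesis (adjusted p = 5.88e-05), defence and immunity markers (8.86e-05), photosynthesis (0.000116), plastid assembly and editing (0.000191), calcium sensors (0.00141), CYP71B (0.00375), glutamate receptor-like and cyclic nucleotide-gated channels (0.0109), tubulins (0.0109), UDP-glycosyltransferases (0.012), endoplasmic reticulum stress (0.012), plastid-encoded photosynthesis genes (0.012), cold and dehydration proteins (0.0375), beta-glucosidases (0.0455) and GH9 endoglucanases (0.0455). At an estimated correlation none of these 14 passed, with adjusted p from 0.0603 for chlorophyll synthesis to 0.702 for the plastid-encoded genes. With camera under the other alternatives GH9 endoglucanases did not pass in 15 of 23 (adjusted p up to 0.559, from 0.0105), beta-glucosidases in 10 of 25 (0.0207 to 0.171), cold and dehydration proteins in 9 of 25 (0.0116 to 0.18) and the plastid-encoded genes in 8 of 25 (4.58e-06 to 0.338). The channels did not pass with camera in 3 of 25 (up to 0.143), and UDP-glycosyltransferases (0.232), calcium sensors (0.0693) and CYP71B (0.0507) in 1 each. The remaining sets passed in all of these alternatives. Fry, which does not compare a set with other genes, gave 0.393 for the plastid-encoded genes and 0.105 for GH9 endoglucanases.

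The 9233 probe sets outside the tested genes, which name no gene or several, also carried differences. Limma called 313 of them for lcs7 against Col-0 at 2 mM calcium, 2270 at 0.3 mM, 205 for low calcium in Col-0, 2915 for low calcium in lcs7 and 510 for the interaction.

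Low calcium was followed by 2915 called genes in lcs7 and 41 in Col-0, a ratio of 71.1. At an unadjusted p under 0.05 the counts were 4491 and 2337, a ratio of 1.92, so the size of the gap depends on the threshold. For called genes, the authors' scaling as the whole cause is argued against by quantile normalization, which left a ratio of 47.6. Disagreement between the Col-0 arrays at 0.3 mM calcium was tested with as many arrays of lcs7 as of Col-0 left out at 0.3 mM. The lowest ratio was 60.6, without Col-0 replicate 1 and lcs7 replicate 1. The Col-0 count fell from 41 to between 20 and 38 without Col-0 replicate 1 and 1 lcs7 array. Since the loss of arrays lowers this small count by itself, the ratios of called genes cannot decide on this cause, which stays open. With 1 array left in each of these groups Col-0 had 1 called gene, too few for a ratio. At an unadjusted p under 0.05 these fits gave ratios from 1.47, with 1 array left, to 2.43. With only Col-0 replicates 2 and 3 left out the ratios were 39.1 for called genes and 1.89 at an unadjusted p under 0.05. Noise at low signals stays open: among genes with a signal of at least 100 in some group the ratio was 4.98 (3493 and 701 genes), between the bounds of 2 and 5 set before the test, and it was 4.81 with an intensity trend on all genes, 5.1 without the 40% dimmest genes and 7.29 with an offset of 50. These settings raised the Col-0 count from 41 to between 480 and 721, while the lcs7 count was between 3392 and 3501. Most of the ratio of 71.1 thus depended on how low signals were handled, and a smaller gap remained. The values lie on both sides of the upper bound, so whether low signals account for the rest was not settled. The biological explanation, a stronger response of the mutant line, stays open too.

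Exchanging arrays between groups gave 10 splits per simple comparison, too few for a share under 0.05. The real split and the highest other split called 367 and 1 genes for lcs7 against Col-0 at 2 mM calcium, 2243 and 0 at 0.3 mM (limma, with 417 to 745 genes at an unadjusted p under 0.05 in the other splits), 41 and 3 for low calcium in Col-0, and 2915 and 1 in lcs7. For the interaction, 6 of 100 splits drawn from 200 called at least the real 308, the real one among the 6, with 2227 as the highest other, so these splits do not exclude chance. They are no test of chance alone, since all 6 keep the genotypes together at 0.3 mM calcium and so hold the real genotype difference there, while the 88 splits that mix them called at most 2.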

How the results depend on the processing

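The offset of 50, the minimum signal of 100 and leaving out Col-0 replicates 2 and 3 at 0.3 mM calcium were tests chosen after the data were seen. In the order lcs7 against Col-0 at 2 mM and 0.3 mM calcium, low calcium in Col-0 and in lcs7, and the interaction, 367, 2243, 41, 2915 and 308 genes were called. Where a comparison is not given for an alternative, its count stayed within 1.5 times. The exception is the interaction with only the compared groups in the fit, which was not run.

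An intensity trend gave 649 genes at 2 mM, 721 for low calcium in Col-0 and 750 for the interaction. Leaving out the 40% dimmest genes gave 639, 665 and 763 with r of 0.564 for the genotype differences and 0.664 for the calcium responses, the offset gave 617, 480 and 794 with r of 0.485 and 0.615, and the minimum signal gave 665, 701 and 811 with r of 0.56 and 0.671. Array weights gave 16 and quantile normalization 68 for low calcium in Col-0. All probe sets, a larger number of tests by construction, gave 735, 4755, 397, 6101 and 985. A fold of at least 2 left 189, 806, 1072 and 187, all but low calcium in Col-0. With only the compared groups in the fit the counts were 83 at 2 mM, 1322 at 0.3 mM and 0 by limma for low calcium in Col-0 (1716 at an unadjusted p under 0.05). With the replicate number as a fixed replicate block they were 220 at 2 mM, 17 for low calcium in Col-0 and 102 for the interaction. The labels do not say that equal numbers share a batch, and residuals of same-number arrays had r from -0.037 to 0.05. Leaving out Col-0 replicates 2 and 3 gave 747 at 0.3 mM, 75 for low calcium in Col-0 and 0 by limma for the interaction (1869 at an unadjusted p under 0.05). The cause of these moves was not tested.

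Leaving out 1 array gave from 138 (without lcs7 replicate 3 at 2 mM) to 421 genes at 2 mM, 1493 (without lcs7 replicate 3 at 0.3 mM) to 2226 at 0.3 mM, 6 (without lcs7 replicate 2 at 0.3 mM) to 79 (without lcs7 replicate 1 at 2 mM) for low calcium in Col-0, 2064 to 3065 in lcs7 and 57 (without lcs7 replicate 3 at 0.3 mM) to 398 for the interaction. The r of the calcium responses ran from 0.231 (without Col-0 replicate 1 at 0.3 mM) to 0.304 and that of the genotype differences from 0.215 to 0.274.

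Of 14127 values of named genes over 27 alternatives, 12911 kept direction and call, 933 lost the call, 282 gained one and 1 changed sign: ndhI for lcs7 against Col-0 at 0.3 mM, 0.062 with quantile normalization. Of 4109 camera values of lists over 27 alternatives, 3910 kept direction and call, 134 lost the call and 65 gained one, and of 155 values with fry 117, 9 and 29. All 47 list calls were lost at an estimated correlation.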

Other observations

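The comparison of Col-0 arrays with the lcs7 level at genes far lower in Col-0, the test for low-calcium lcs7 material, the test for low calcium acting on Col-0 and the test of chromosome regions were chosen after the results were seen; the tests of genes lower in lcs7 and of neighbouring genes were chosen before.

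In further groups a few members were called for low calcium in lcs7. Of 15 SWEET sugar transporters 3 fell, SWEET10 (-1.97 ± 0.37), SWEET16 (-1.50 ± 0.27) and SWEET4 (-1.33 ± 0.30). Enzymes of succinate, isocitrate and citrate metabolism rose in 5 of 14 cases, SDH1-1 most (1.17 ± 0.20), and ACLB-1 fell (-0.43 ± 0.09). Among 10 genes of autophagy ATG8B, APG8A and ATG8D rose (0.70, 0.67 and 0.49), while ATG8E (-0.90) and ATG8F (-0.33) fell. The ubiquitin ligase genes PUB23 (2.64 ± 0.50), PUB24 (1.46 ± 0.19) and PUB43 (0.87 ± 0.18) were the called ones of 9. None of these 4 sets passed camera (adjusted p = 0.339, 0.0983, 0.523 and 0.0545).

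Cell wall genes of lcs7 at low calcium went both ways. The cellulose-related, xyloglucan and expansin, pectin and early auxin lists given here did not pass camera. Since 2915 of all 13356 genes were called in this comparison, called members alone do not set these lists apart. The cellulose-related gene COB fell (-1.24 ± 0.14) with 3 others of 10 (4 when adjusted over the list alone), and the expansin-like genes EXLA1 (-1.87 ± 0.33) and EXLB1 (-1.22 ± 0.24) fell while XTH19, EXPA20 and XTH32 rose, XTH19 by 2.43 ± 0.73, of 29 xyloglucan and expansin genes (3 and 2 when adjusted over the list alone). The pectin methylesterase genes ATPMEPCRB (2.47 ± 0.29) and PMEPCRF (1.41 ± 0.21) rose and GAUT15 fell (-0.64 ± 0.14), of 7 pectin genes (also 2 and 1 when adjusted over the list alone). Of 21 beta-glucosidases 7 rose, such as BGLU31 (4.54 ± 0.84, or 2.36 with the lower signal at 20), and BGLU33 (-1.25 ± 0.25) and BGLU16 (-0.61 ± 0.12) fell (camera adjusted p = 0.0254, and 0.209 at an estimated correlation). With camera under the other alternatives the beta-glucosidases did not pass in 3 of 26 (adjusted p from 0.00929 to 0.0836). Of 12 early auxin response genes GH3.3 rose (0.91 ± 0.22) and IAA20, IAA29 and IAA18 fell (-2.66, -1.48 and -1.02, or -0.89 for IAA20 with the lower signal at 20), also 1 and 3 when adjusted over the list alone.

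Col-0 replicates 2 and 3 at 0.3 mM calcium stood at 25.5 and 37.2% of the lcs7 level at 11 genes at least 8-fold lower in Col-0 at 2 mM calcium. Shoots of lcs7 from 0.3 mM calcium mixed into these samples are argued against by 23 genes high only in that group, at which the higher upper quartile of the arrays was 6.7%. Material with the line differences but without the low-calcium response stays open: at 16 genes lower in lcs7 the replicates 1, 2 and 3 stood at 46.6, 40.4 and 42.6% of the way, so these genes do not part the arrays. For 77 genes higher in lcs7 no prediction was written, and they were also chosen without the Col-0 arrays at 0.3 mM calcium. At these genes replicates 1, 2 and 3 stood at 7.5, 19.1 and 23.1%, against -0.4 to 0.4% in the arrays at 2 mM. The 2 mM arrays set the 0% level and entered the choice of genes, so other Col-0 arrays could lie above them without a response. Replicates 2 and 3 lay higher than replicate 1. No gene met the rule for a test of lcs7 from 2 mM calcium. Low calcium acting on Col-0 stays open as well, since replicate 1 alone lay within the range of the arrays at 2 mM at the 11 genes (-0.1%). The 77 genes cannot decide this, because of how they were chosen. At the 11 genes the upper quartiles of replicates 2 and 3 were 29.6 and 41.3%, against lower quartiles of 60.1 to 65.5% in lcs7 at 2 mM. These values argue against whole lcs7 samples under a Col-0 label. The 11 genes ran from 1.3 to 65.2% in replicate 2 and from 1.5 to 67.8% in replicate 3. No single share of lcs7 material thus accounts for all of them. A mixed sample and a response of these seedlings may each explain part of the pattern.

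Of the 123 higher and 97 lower genes called in lcs7 at both calcium levels, 218 are among the 13217 tested genes placed on the nuclear chromosomes. They lay closer together than random genes and made 33 neighbouring pairs within 5 tested genes, against a mean of 17.9 for random sets (permutation p = 0.0013; 10000 permutations) and of 19.2, at most 31, for sets of genes called for low calcium in lcs7, and the variance over mean of their number per run of about 100 tested genes was 2.61, where the highest of 1000 random sets was 1.36 and of 1000 low-calcium sets 1.55 (p = 0.001, the smallest these sets can give). Of 132 runs 15 held 94 of the 218, and AT1G identifiers made up 81 of them, 2.37% of the tested ones, against 0.51% for AT2G identifiers. The locus of AVP1 lies in a run with 1 of these genes, and the runs before and after it held 5 and 7, where 1.65 per run are expected. The highest count, 11, was in a run of AT5G identifiers. Nearness to AVP1 was not tested. These values are consistent with inherited line differences in blocks of genes, such as sequence left from another background, as a source of part of the lcs7 differences. Some locus names of the largest changes had been seen before the neighbour test, and with 1 mutant line the effects of AVP1 and of other differences of the line are not separated.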
